A study of Mus musculus with 105 samples.

How the data were processed

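Small RNA and messenger RNA were measured in mouse cells. The cells were CIMEF (contact-inhibited mouse embryonic fibroblasts, which have stopped dividing), DMEF (passaged fibroblasts that keep dividing), ESC (an embryonic stem cell line) and a contact-inhibited fibroblast culture that lacks Cyrano (gene Oip5os1), a long noncoding RNA. Cells were fed 5-ethynyluridine (5EU), a uridine analogue that enters newly made RNA and allows that RNA to be tagged and pulled down. The dose was 400 µM for fibroblasts and 125 µM for ESC, per the labels. An EU library holds the small RNA that was pulled down after a given time of labelling, and an input library holds the small RNA of the same cells before the pulldown. A set of such libraries from 1 culture, ordered by labelling time, is called a time course here.

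The series holds 105 samples and 15 tables, of which all 100 columns were used. There were 7 time courses, 2 for each of the 3 wild-type lines and 1 for the knockout. CIMEF was sampled at 0, 1, 2, 4, 8, 24, 72 and 168 h (1 week), DMEF up to 72 h and ESC at 0, 1, 2, 4, 8, 16 and 24 h. The 0 h libraries belong to replicate 1 of each wild-type line, and the knockout course starts at 2 h. Of the DMEF samples, 5 EU samples of course 2 are second sequencing runs. Their table has 1 column per time, which may hold either run or the sum of both, and each column was taken as 1 library.

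All values are the raw read counts that the authors deposited, 1 value per mature miRNA or per gene, with no normalization. The small-RNA tables hold 1013 miRNAs and 8 further features, which are synthetic RNA standards and size markers. Per the submitters' processing notes, adapters were removed with cutadapt, and the notes of most samples also name STAR 2.4 and HTSeq 0.9.1 with the mouse genome mm10/GRCm38. The notes of the knockout samples and of ESC course 2 name cutadapt only. Whether the random bases of the adapters were used to remove duplicate reads is not recorded, so the counts were taken as reads. Of 54532 gene identifiers in the mRNA table, 54409 were paired with a symbol through the reference tables, and 32500 had at least 1 count. Coordinates are those of the GRCm38.p6 annotation, the build that the notes name.

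Input libraries held 912688 to 9117300 miRNA counts, EU libraries 1196 to 2463188 and mRNA libraries 23030907 to 34093791 counts. The EU range includes the 0 h libraries, which measure background, with 21334 counts in CIMEF, 2262 in DMEF and 1196 in ESC. CPM of miRNAs per line and of mRNAs means the count divided by the total after scaling by edgeR and multiplied by 1e+06, with miRNA counts summed per time course. CPM of miR-7a-5p in single input libraries, and their means per time course, use the unscaled miRNA total of the library. Intervals and floors given with counts cover counting error only, since reads from one library are not independent molecules. A count of 0 allows up to 3 counts, and folds against a line without a count were computed against 3 counts over the summed libraries of that line. Such folds and ratios use the same scaled totals as the CPM per line, with counts summed over both courses. Ratios against 1 to 3 counts carry exact binomial 95% intervals, and log2 values against more counts than that are fitted values without such an interval.

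Differences in counts were tested with edgeR 4.0.16 (TMM scaling, its expression filter, quasi-likelihood test) in R 4.3.3. Input counts were summed over the time points of a course, so that the time courses were the replicates, and the 7 courses shared 1 dispersion fit for the contrasts CIMEF minus DMEF, ESC minus DMEF and ESC minus CIMEF. The 6 mRNA libraries were fitted in the same way. The effect of labelling time on input levels was tested per line as the slope on log2(hours + 1), and the difference of slopes between lines as an interaction. The knockout was compared with both wild-type CIMEF courses over the 6 shared times, library by library, for input and EU libraries apart. All model p-values are two-sided, were adjusted by the Benjamini-Hochberg method over the features of a contrast, and passed at 0.05. They measure only the spread between these libraries or time courses. DESeq2 1.42.0 was run beside edgeR. With counts summed per course, and for half-lives, the knockout is 1 sample, and its tests take their spread from the other courses. In the library-by-library fits all knockout libraries come from 1 course, so time points stand in for replicates there.

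Half-lives were fitted per miRNA and course as y = A(1 - exp(-kt)), where y is the EU count per standard count less the 0 h value, and the half-life is ln 2 over k. The fit was weighted least squares on the log scale with weights from a noise of 0.2 and the counting error, over a grid of 400 half-lives from 0.25 h to 10 times the last time (1680 h in CIMEF and the knockout, 720 h in DMEF, 240 h in ESC). Values at either end of the grid are limits, and were left out of tests of differences. MiRNAs needed a mean input count of 50, EU counts of 100 over the course and 4 usable times. In dividing cells k includes dilution by growth, which was not separated from decay. The product of A and k was used as the production rate.

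Both of the following choices departed from, or filled in, the written plan. The plan named the sum of the standards without naming features. Of the standards, 3 (22, 24 and 26 nucleotides long) were found almost only in EU libraries, and their sum was chosen as the divisor after the counts of the standards and the labelling curves had been seen and before any half-life was fitted. The sequencing standards, present in both kinds of library, and the sum of all standards were added as alternatives. For courses without a 0 h library, the 0 h value of replicate 1 was rescaled by the ratio of total miRNA per standard at the last time point.

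Log2 half-lives were compared between lines with limma 3.58.1 over the 7 courses. A first version of that step, which estimated the spread per contrast, was replaced after its counts had been seen, because the plan called for 1 fit of all courses. For each hairpin with both arms measured, the guide (the arm with more input counts in that line) was set against the passenger by a two-sided sign-flip permutation test with 100000 resamples, or an exact one with fewer than 10 hairpins. Correlations of production rate and half-life with input share were taken across miRNAs within a line, over 6 relations, and the half-lives of a list's guides were compared with those of other guides by two-sided permutation, for lists with at least 4 measured members. These used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with plots by matplotlib 3.10.9.

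Lists of genes were written before the data were examined, as were the comparisons, their tests, and most of the other settings. The 15 miRNA lists were the let-7 family, miR-17-92 and its paralogs, miR-290-295 with miR-302, the miR-15/16 family, the Dlk1-Dio3 cluster, the Sfmbt2 cluster, mesenchymal miRNAs, the miR-34 family, miR-29 with miR-30, the miR-200 family, mirtrons, and markers of hematopoietic, muscle, neural, and endothelial or liver cells. The 23 mRNA lists covered the cell cycle, CDK inhibitors and growth arrest, pluripotency, extracellular matrix, YAP targets, actin and serum response, interferon response, miRNA machinery, miRNA host genes, p53 targets, cholesterol synthesis, lysosome and autophagy, glycolysis, ribosome biogenesis, imprinted genes, and markers of macrophage, endothelial, epithelial, muscle, neural, adipocyte, early differentiation and two-cell-like cells. No member of the last list passed the expression filter, which left 22 to be tested. Lists were tested with camera at its preset correlation and again with an estimated correlation.

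Named genes followed a written rule. Among features past the threshold and above the median level, the 5 largest changes each way were named per contrast (predicted genes and genes not used here left out), with the members of a list that changed most. For half-lives the 5 shortest and longest guides measured in both courses within a 2-fold spread were named, and the 5 largest differences each way between lines. For the knockout, miR-7a-5p, miR-7b-5p and the 5 smallest p-values each way were named. The 10 miRNAs with the lowest p between CIMEF and DMEF were named after their values were seen, since none passed.

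The main fits were tested on simulated data with known changes. In the CIMEF and DMEF miRNA comparison (787 features) 53% of 2-fold and 100% of 4-fold changes were recovered, and in the mRNA comparison (17423 genes) 17.2% and 88%. For the knockout input comparison (502 miRNAs) both shares were 100%. For the slope on labelling time in CIMEF (486 miRNAs) the shares were 85.1% and 100%. Of the calls in these count simulations, 1.29% (miRNA levels) to 7.08% (mRNA) were false. They used 1 fixed dispersion and no differences between courses. In the real data the log2 difference between the CIMEF courses had an SD of 1.79 over 812 miRNAs. Recovery in the data can therefore be lower than these shares. Simulated half-lives of 8 h came back inside the limits and within 2-fold for 98.2% of all simulated miRNAs in CIMEF, 95.0% in DMEF and 84.2% in ESC. At 128 h the shares were 57.3%, 29.4% and 11.5%. Simulated half-life differences of 3 on the log2 scale, among 300 miRNAs, were all recovered (100%). The simulated half-lives involved no standards, no subtraction of a 0 h value and only the noise that the weights assume. The simulated differences had a fixed spread. Between the real CIMEF courses 67.3% of miRNAs lay within 2-fold after removal of the median shift. Half-lives in the data can therefore be recovered less well than these shares.

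Other settings were another test, sums without the 0 h libraries, no expression filter, another unit of replication, a replicate block, leaving out each replicate, and, for half-lives, EU share over input share, no subtraction, a lag of 0.5 h, times up to 24 h, a mean input count of 500 and an unweighted fit. The alternative with another pseudocount was not run, because every table held counts. Alternatives chosen after seeing the data were both other sums of standards, leaving out the 1 h libraries, centring half-lives on the median of a course or on the median of the 68 miRNAs measured in every course, keeping limits at the grid edge, splits of the wild-type courses as controls, and leaving out the gene Gm42418, which overlaps ribosomal RNA and held 1.22% to 7.95% of the mRNA counts.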

Results

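The samples trace how fast mouse cells make and lose microRNAs (miRNAs), short RNAs that repress messenger RNAs. CIMEF contributed 15 EU and 15 input libraries, DMEF 18 EU samples and 13 input libraries, ESC 13 of each, and the Cyrano knockout 6 of each. Messenger RNA was measured in 2 libraries per wild-type line. Per time course, input libraries held 2900666 to 9117300 miRNA counts in CIMEF course 1, 3563776 to 4797165 in CIMEF course 2, 5543048 to 7807121 in the knockout, 1247238 to 8355239 and 912688 to 1747943 in the DMEF courses, and 1778102 to 3983530 and 2555530 to 3546935 in the ESC courses. EU libraries were shallower, with 21334 to 598887 and 137943 to 2463188 miRNA counts in the CIMEF courses, 284662 to 878744 in the knockout, 2262 to 373170 and 219919 to 498340 in DMEF, and 1196 to 102412 and 13137 to 131117 in ESC. The mRNA libraries held 26753699 and 23030907 counts in CIMEF, 29083076 and 34093791 in DMEF, and 25828188 and 23285365 in ESC. Summed miRNA profiles of both courses correlated across miRNAs (not independent replicates) with r = 0.91 in CIMEF, 0.99 in DMEF and 0.99 in ESC, and 223 of 812 miRNAs differed by over 2-fold between the CIMEF courses.

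Embryonic stem cells and fibroblasts carried different sets of miRNAs. The miR-290-295 and miR-302 clusters, which are transcribed in early embryos and pluripotent cells, made up a large part of the ESC profile and were almost absent from fibroblasts. Fibroblasts carried let-7, which accumulates as cells differentiate, together with miR-214, miR-199 and miR-99a, all known from mesenchymal tissue. The miR-200 family of epithelial cells and the miR-17-92 group, which promotes proliferation, were higher in ESC. This comparison asks which miRNAs set the cell states apart before their turnover is compared.

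Of 812 miRNAs tested, 185 were higher and 203 lower in ESC than in DMEF, and 222 were higher and 237 lower than in CIMEF. Without ESC course 1 the calls numbered 208 and 268, and without ESC course 2 219 and 291. All 12 members of miR-290-295 and miR-302 were higher in ESC in both contrasts, also adjusted over the list alone. Their summed level was 359309 ± 9623 CPM in ESC (SD, n = 2), 2.16 CPM in DMEF and 1.04 CPM in CIMEF. MiR-302b-3p reached 2006 ± 935 CPM in ESC and had no count in DMEF, so it was at least 28029-fold higher. With no DMEF count either, miR-302d-3p was at least 23395-fold and miR-295-5p at least 19056-fold higher in ESC. MiR-290a-5p stood at 27584 ± 4560 CPM in ESC against 3 counts in DMEF, a ratio of 383834 (95% interval 131341 to 1861250). MiR-293-3p was higher by a log2 of 17.84 than in DMEF and 18.90 than in CIMEF, and miR-291a-3p by 18.72 than in CIMEF. MiR-294-5p had no count in CIMEF and was at least 68162-fold higher in ESC, and miR-292a-3p averaged 28048 CPM in ESC against 2 counts in CIMEF, a ratio of 855565 (95% interval 236844 to 7064680). The annotation places Mir290a on chromosome 7 at 3218626 to 3218708 and Mir302a on chromosome 3 at 127545496 to 127545564.

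Lower in ESC were all 11 let-7 hairpins in both contrasts, with the same count adjusted over the list alone. Let-7 summed to 1120 ± 758 CPM in ESC, 90806 ± 20255 CPM in DMEF and 164450 ± 24789 CPM in CIMEF. Let-7b-5p differed by a log2 of -12.34 from DMEF and -13.43 from CIMEF. MiR-214-5p had no count in ESC and was at least 15926-fold lower than in DMEF and at least 25106-fold lower than in CIMEF. Its partner miR-214-3p had 2 counts in ESC, 207694-fold below DMEF (95% interval 57495 to 1715000). MiR-206-3p, a muscle miRNA, was lower than in DMEF by a log2 of -11.80, and miR-99a-5p lower than in CIMEF by -13.21. MiR-125b-2-3p had no count in ESC and was at least 711-fold lower than in CIMEF. Of 25 mesenchymal miRNAs, 21 were lower than in DMEF and 23 than in CIMEF, or 21 and 24 adjusted over the list alone.

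Among the other lists, counts are over all miRNAs, and those adjusted over the list alone were equal unless given. All 5 members of the miR-200 family and 10 of 13 of the miR-17-92 group were higher in ESC in both contrasts. All 4 of the miR-34 family were lower in both, as were 5 (DMEF) and 8 (CIMEF) of 8 in miR-29 and miR-30. For the miR-15/16 family 2 were higher and 1 lower than in DMEF (2 and 3 adjusted over the list alone), and 4 of 8 were lower than in CIMEF. The Dlk1-Dio3 cluster, imprinted and large, had 2 of 45 members higher than in DMEF and 3 than in CIMEF (0 in both contrasts adjusted over the list alone), and the Sfmbt2 cluster 4 and 13 of 35 (3 and 5 adjusted over the list alone). Mirtrons had 2 and 1 of 5 lower. Hematopoietic markers had 2 higher and 2 lower of 6 against DMEF, and 2 higher and 1 lower against CIMEF. Muscle markers had 1 higher and 3 lower of 6, then 1 higher and 2 lower. Neural markers had 2 of 6 higher, then 2 higher and 2 lower. Endothelial or liver markers had 1 higher and 1 lower of 2, then 1 higher (0 adjusted over the list alone). Median and mean log2 differed in sign against DMEF for miR-15/16 (-0.81 and 0.30) and for hematopoietic markers (-2.27 and 0.78), and again for the latter against CIMEF (-1.27 and 2.15). With camera's preset correlation let-7 passed against DMEF (adjusted p = 1.0e-05), but the list had adjusted p = 0.417 with an estimated correlation, and no miRNA list in any contrast passed with an estimated correlation.

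Between contact-inhibited and dividing fibroblasts the tools differed on which miRNAs passed. The miRNAs with the lowest p-values, none of which passed in edgeR, included miR-7a-5p, estimated lower in CIMEF, and the miR-15/16 relatives miR-195a-5p and miR-497a-5p, which restrain the cell cycle and were estimated higher. MiR-708-5p and miR-181a-5p, the latter a regulator of differentiation, were estimated higher as well. The contrast asks which miRNAs go with exit from the cell cycle.

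None of the 812 miRNAs passed in edgeR (0 calls), while 158 had an unadjusted p below the threshold and DESeq2 called 110. The lowest adjusted p was 0.0751 in edgeR, shared by more than the 10 miRNAs with the lowest p. Among those 10 were miR-7a-5p (log2 -3.02, SE 0.37), miR-708-5p (4.50, SE 0.65), miR-195a-5p (3.99, SE 0.58), miR-497a-5p (3.73, SE 0.55), miR-322-3p (3.35, SE 0.48) and miR-181a-5p (2.41, SE 0.39). Without CIMEF course 1 edgeR called 207, and without CIMEF course 2 it called 49. Adjusted over the list alone, 6 of 8 in the miR-15/16 family were higher in CIMEF, 5 of 13 in the miR-17-92 group lower, 1 of 8 in miR-29 and miR-30 higher, and 1 of 5 mirtrons lower. Each of the other 11 lists had 0 calls both ways, and no list passed camera with an estimated correlation (lowest adjusted p = 0.585). At the preset correlation miR-15/16 passed upward (adjusted p = 4.9e-04, or adjusted p = 0.585 with an estimated correlation). The miR-17-92 group passed downward there (adjusted p = 0.00894, or adjusted p = 0.585 with an estimated correlation), as did the Sfmbt2 cluster (adjusted p = 0.00499, or adjusted p = 0.585 with an estimated correlation). The Dlk1-Dio3 cluster passed downward too, while its median log2 was 0.042 and its mean -0.025, and mirtrons had a median of 0.31 and a mean of -0.87. Its summed level was 7338 ± 10198 CPM in CIMEF, where both courses differed widely, 5433 ± 1789 CPM in DMEF and 42889 ± 2715 CPM in ESC (SD, n = 2).

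Many messenger RNAs passed in edgeR between contact-inhibited and dividing fibroblasts, where no miRNA did. The log2 difference between CIMEF replicates had an SD of 0.55 for mRNA and 1.79 for miRNA. The numbers of calls therefore do not show which kind of RNA separates the states better. Genes of the actin cytoskeleton that respond to serum (Acta2, Tagln, Cnn1), genes that build ribosomes (Nop2, Rrp12 and their regulator Myc) and mitotic genes (Plk1, Aurka) were lower in CIMEF. Gas1, Cdkn1c, Eln, Dcn and Postn were higher, while growth-arrest and matrix genes as groups went both ways. Ccn1 and Ccn2, targets of the YAP pathway that senses cell crowding, were lower, though other targets were higher. Among interferon-response genes 9 of 18 passed as higher and 0 as lower, with Oasl2 and Ifit1 higher.

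Of 18094 genes, 3528 were higher and 3812 lower in CIMEF than in DMEF. DESeq2 called 6789 in all, and without DMEF replicate 2 edgeR called 3605. The largest increases were in Eln (ENSMUSG00000029675; log2 6.60, SE 1.18, adjusted p = 0.00595), with 978 ± 1169 CPM in CIMEF and 10.1 ± 4.73 CPM in DMEF (SD, n = 2), and in Acpp (6.28), Phex (6.25), Agtr2 (6.19) and Car9 (5.98). Both CIMEF libraries lay far apart for Eln, and also for Acpp (50.7 ± 44.4 CPM) and Car9 (38.3 ± 27.8 CPM). Among the largest decreases were those in Arhgap36 (ENSMUSG00000036198; log2 -6.91, SE 0.28, adjusted p = 1.9e-04), Ripor2 (-6.40), Alkal1 (-6.03) and Anxa8 (-5.07). Arhgap36 had 1.76 ± 0.338 CPM in CIMEF and 211 ± 21.6 CPM in DMEF (SD, n = 2).

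**Figure D1:**
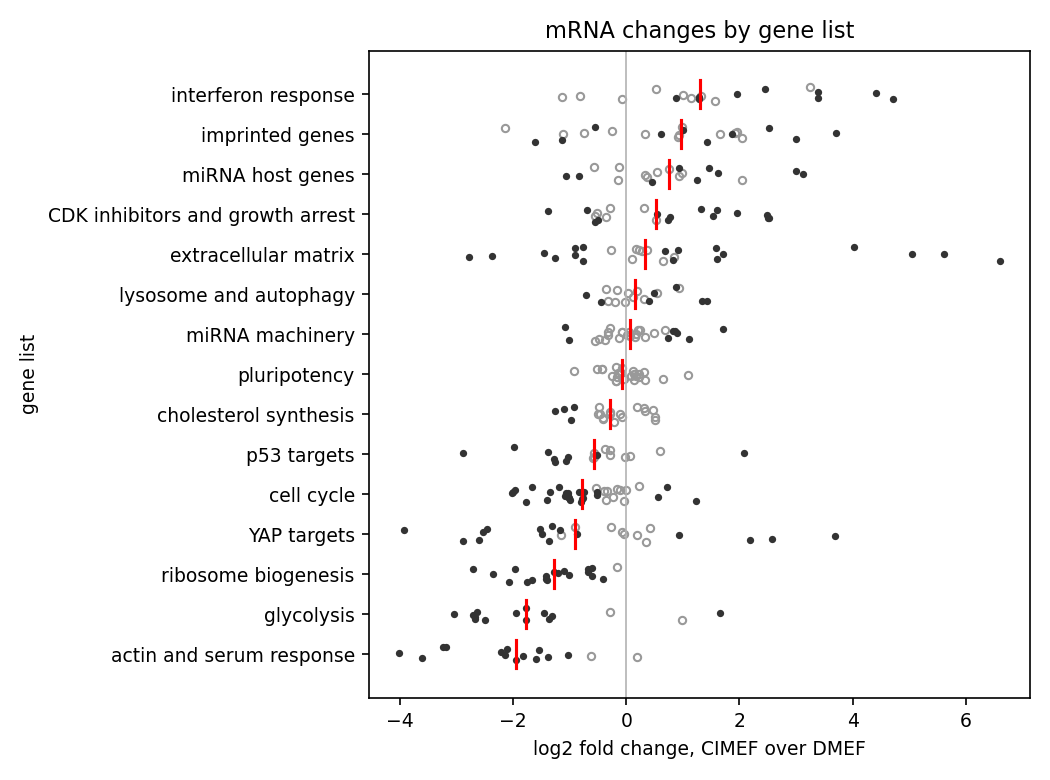
Log2 fold change of CIMEF over DMEF for each member of the 15 mRNA lists with at least 15 tested gene identifiers. Filled points passed at an adjusted p of 0.05 in edgeR, open points did not, and red bars are list medians. The lowest medians are those of actin and serum response (-1.96), glycolysis (-1.77) and ribosome biogenesis (-1.27).

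In the lists, counts adjusted over the list alone were equal to those over all genes unless given. Actin and serum response had 13 of 15 genes lower in CIMEF (Acta2 log2 -3.19, Tagln -3.61, Cnn1 -3.24), ribosome biogenesis 18 of 19 (Myc -2.70, Rrp9 -2.35), and glycolysis 12 of 15 lower and 1 higher (Ldha -2.71, Pkm -2.67). In the glycolysis list at least 1 symbol matched more than 1 identifier, so its 15 entries are identifiers and not 15 genes. Eno1, Aldoa and Gapdh may share reads with processed pseudogenes, which was not measured here, so their counts are uncertain. The cell cycle had 22 of 35 lower and 3 higher (24 and 3 adjusted over the list alone; Plk1 -2.02, Rrm2 -1.97, Ube2c -1.77). CDK inhibitors and growth arrest had 10 of 20 higher and 4 lower (11 and 5 adjusted over the list alone; Cdkn1c 2.53, Gas1 2.49). Extracellular matrix had 10 of 26 higher and 8 lower (11 and 8 adjusted over the list alone; Lum 5.62, Dcn 5.05, Postn 4.03). YAP targets had 11 of 23 lower and 4 higher (Ccn2 -2.89, Ccn1 -2.61, Igfbp3 3.68), interferon response 9 of 18 higher, p53 targets 8 of 18 lower and 1 higher, and cholesterol synthesis 4 of 20 lower. Lysosome and autophagy had 5 of 18 higher and 2 lower, imprinted genes 7 of 22 higher and 3 lower (Airn 3.70), miRNA host genes 7 of 19 higher and 2 lower (Mest 3.00), and miRNA machinery 6 of 27 higher and 2 lower (Tut4 1.71, Snd1 -1.09). None of 25 pluripotency genes passed in edgeR, and none of 7 epithelial markers. Markers of other cells had 1 of 2 higher (macrophage), 1 of 6 higher and 2 lower (endothelial, median log2 0.21 but mean -0.046), 2 of 5 lower (muscle), 2 of 6 higher and 3 lower (neural, Nes -3.21), 1 of 4 higher and 3 lower (adipocyte) and 1 of 8 lower (early differentiation). Camera's preset correlation passed actin and serum response (adjusted p = 2.6e-06), ribosome biogenesis, the cell cycle, glycolysis and interferon response, and each of these 5 had adjusted p = 0.735 with an estimated correlation.

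ESC expressed pluripotency genes and had lower levels of most matrix and actin genes than the fibroblasts. Dppa2, Zfp42, Utf1 and Gdf3 mark naive stem cells and were high only in ESC among these lines. Collagens and matricellular genes (Col5a2, Thbs1) and smooth-muscle actin genes were far lower. Lin28a and Lin28b, which block let-7 maturation, were higher in ESC, where let-7 was low. Epithelial junction genes (Cdh1, Epcam, Cldn4) were higher in ESC, which grow as epithelial colonies.

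In ESC 5488 genes were higher and 5513 lower than in DMEF, and 6914 higher and 6814 lower than in CIMEF. The largest increases over DMEF were in Platr10 (log2 7.69), Ildr1 (7.68), Dppa2 (7.54), Dsg2 (7.52) and Arl14epl (7.52), and over CIMEF they included Fut9 (8.09), Ildr1 (8.03), Triml1 (7.80) and Apela (7.79). The largest decreases were in S100a7a (-7.68), Inhba (-7.54), Ptgs2 (-7.53), Col10a1 (-7.42) and Alkal1 (-7.36) against DMEF, and in Cxcl15 (-7.90), Grin3a (-7.86), Omd (-7.77), Fxyd1 (-7.73) and Trabd2b (-7.64) against CIMEF. Both CIMEF libraries lay far apart for Cxcl15 (140 ± 162 CPM) and Trabd2b (179 ± 202 CPM; SD, n = 2). All 25 pluripotency genes were higher in both contrasts (Gdf3 7.32 over DMEF, Utf1 7.61 over CIMEF), and all 15 actin genes lower (Tagln -7.22, Acta2 -7.17 against DMEF). Of 26 matrix genes, 24 were lower than in DMEF (Col5a2 -6.87, Thbs1 -6.83) and 25 than in CIMEF. Ribosome biogenesis had 18 and 19 of 19 genes higher (Dkc1 2.13 over DMEF), and cholesterol synthesis 15 higher, then 14 higher and 1 lower of 20 (15 and 1 adjusted over the list alone). Lin28a was higher by a log2 of 7.15 and Lin28b by 6.56 than in DMEF, and Ago4 lower by -4.71.

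For the other lists the DMEF contrast comes first and the CIMEF contrast second, and counts adjusted over the list alone were equal unless given. Epithelial markers had 6 higher and 1 lower, then 6 higher of 7. The cell cycle had 15 higher and 4 lower (15 and 3 adjusted over the list alone), then 26 higher and 4 lower of 35. CDK inhibitors and growth arrest had 1 higher and 14 lower (1 and 15 adjusted over the list alone), then 16 lower of 20. YAP targets had 1 higher and 18 lower (2 and 20 adjusted over the list alone), then 1 higher and 17 lower of 23. Interferon response had 5 higher and 8 lower, then 3 higher and 12 lower of 18. MiRNA machinery had 14 higher and 7 lower, then 13 higher and 10 lower of 27, and miRNA host genes 4 higher and 11 lower, then 4 and 12 of 19. For p53 targets there were 3 higher and 9 lower, then 4 and 5 of 18, and for lysosome and autophagy 3 and 13, then 2 and 11 of 18. Glycolysis had 6 higher and 5 lower (7 and 5 adjusted over the list alone), then 13 higher of 15. Imprinted genes had 6 higher and 9 lower (median log2 0.20, mean -0.15), then 5 and 12 of 22. Markers of other cells went both ways, with endothelial 3 and 2, then 3 and 1 of 6, muscle 3 and 1, then 4 and 0 of 5, and neural 3 and 2 in both of 6. Adipocyte markers had 1 higher and 2 lower (1 and 3 adjusted over the list alone), then 1 and 3 of 4. Early differentiation had 4 and 2 in both of 8, and macrophage 1 and 0, then 1 and 1 of 2. Pluripotency passed camera at the preset correlation and had adjusted p = 0.431 (DMEF) and 0.445 (CIMEF) with an estimated correlation, and no mRNA list passed in any contrast with an estimated correlation.

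Long exposure to 5EU went with shifts in some input miRNAs. In CIMEF miR-92a-3p, miR-17-5p and miR-20a-5p of the proliferative miR-17-92 cluster rose over the course, and the linked miR-503-5p and miR-322-5p, which restrain the cell cycle, fell. In DMEF miR-21a-3p and members of the Dlk1-Dio3 cluster (miR-376a-3p, miR-136-5p) fell. In ESC miR-34a-5p, a p53 target, and miR-200 members (miR-200a-3p, miR-200b-3p, miR-429-3p) rose. The test asks whether input levels stayed steady during labelling, which the half-life model assumes, and time in culture cannot be told apart from 5EU in it.

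In CIMEF 64 miRNAs rose and 63 fell of 497, in DMEF 61 and 54 of 447, and in ESC 22 and 4 of 550. The median absolute slope of the called miRNAs was 0.09 log2 units per doubling of hours + 1 in CIMEF, 0.08 in DMEF and 0.21 in ESC. Named slopes were 0.16 for miR-92a-3p, 0.15 for miR-17-5p, 0.14 for miR-20a-5p, 0.13 for miR-29b-3p, 0.12 for miR-155-5p, -0.32 for miR-503-5p, -0.22 for miR-351-3p, -0.17 for miR-450b-5p, -0.14 for miR-326-3p and -0.13 for miR-322-5p in CIMEF. In DMEF they were 0.11 for miR-501-3p, miR-324-3p and miR-532-5p, 0.10 for miR-3102-3p and miR-30c-5p, -0.23 for miR-21a-3p, -0.21 for miR-135a-5p and miR-376a-3p, and -0.19 for miR-136-5p and miR-33-5p. In ESC they were 0.23 for miR-34a-5p, 0.21 for miR-200a-3p, 0.17 for miR-429-3p and miR-200b-3p, 0.13 for miR-193b-3p and -0.09 for miR-20a-3p. Counts moved when a course was left out. CIMEF gave 29 without course 2, DMEF 23 without course 1 and 50 without course 2, and ESC 8 without course 1 and 0 without course 2 (edgeR; 32 by DESeq2 with both).

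MiRNAs lasted longest in contact-inhibited fibroblasts. MiR-7a-5p, which extensive pairing to Cyrano can mark for decay, was short-lived in all 3 lines. MiR-503-5p, known for fast turnover, was also short-lived in CIMEF. The proliferative miR-20a-5p was long-lived there. Input of miR-503-5p fell and that of miR-20a-5p rose during labelling, which the fit takes as faster and slower turnover. In DMEF several Dlk1-Dio3 miRNAs (miR-154-3p, miR-376b-3p, miR-543-3p) turned over fast. The comparison asks how fast miRNAs turn over in each state.

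Median half-lives were 83.3 h (283 miRNAs) and 51.3 h (293) in the CIMEF courses, 13.8 h (278) and 10.9 h (266) in DMEF, 9.61 h (139) and 10.3 h (200) in ESC and 19.8 h (286) in the knockout. They depended on the standards, whose use was fixed only after their counts had been seen. With the sequencing standards the medians were 17.8 and 16.6 h in CIMEF, 3.56 and 1.51 h in DMEF, 16.1 and 3.48 h in ESC and 3.62 h in the knockout. With all standards summed they were 18.1 and 56.0 h, 3.63 and 4.80 h, 9.61 and 10.3 h, and 21.0 h. That sum is nearly all sequencing standards in CIMEF course 1 and nearly all the other standards in the knockout, so it does not treat courses alike. At 0 h, the background, CIMEF had 31.1 miRNA counts per standard count, above the 16.8 at 1 h, so subtraction removed the 1 h point of 187 of 283 and 153 of 293 miRNAs. DMEF had 4.47 against 31.0, and ESC 0.00540 against 0.0585. Half-lives at the upper limit numbered 57 and 44 in the CIMEF courses. Half-lives of both courses of a line correlated across miRNAs (not independent replicates) with r = 0.84 in CIMEF, 0.88 in DMEF and 0.55 in ESC.

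**Figure D2:**
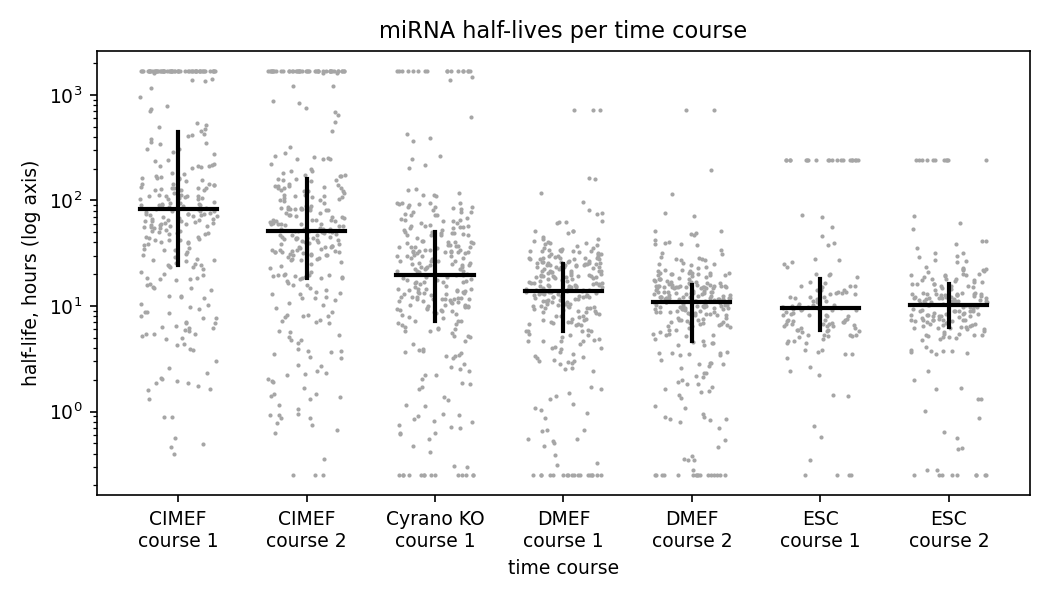
Half-life of each miRNA (points, hours on a log axis) in each of the 7 time courses, with the median (horizontal bar) and quartiles (vertical bar); points aligned at the top or at 0.25 h are limits of the fit. Medians are 83.3 and 51.3 h in CIMEF, 19.8 h in the knockout (KO), and 9.61 to 13.8 h in DMEF and ESC; with other standards these values differ.

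Guides are ranked here only where both courses lay within a 2-fold spread, which held for 53 guides in CIMEF, 129 in DMEF and 71 in ESC. Longer values in CIMEF and ESC and shorter values in ESC lay outside these sets, and limits were left out. In DMEF miR-222-3p (77.7 h) and miR-125b-5p (59.4 h), also outside, were longer than all but the first of the longest named there. In CIMEF the shortest-lived of these were miR-7a-5p (4.13 h as the geometric mean of 4.82 and 3.54 h), miR-503-5p (5.76 h), miR-672-5p (14.4 h), miR-676-3p (15.5 h) and miR-450b-3p (17.4 h). The longest-lived were miR-20a-5p (223 h), miR-296-5p (179 h), miR-181a-5p (163 h), miR-574-5p (137 h) and let-7d-5p (135 h). In DMEF the shortest were miR-154-3p (1.07 h), miR-376b-3p (1.92 h), miR-7a-5p (2.12 h), miR-665-3p (2.27 h) and miR-543-3p (3.38 h), and the longest miR-181c-5p (85.9 h), miR-224-5p (49.6 h), miR-132-3p (41.4 h), miR-101a-3p.2 (37.5 h) and miR-30d-5p (35.3 h). In ESC the shortest were miR-370-3p (4.17 h), miR-7a-5p (4.39 h), miR-134-5p (4.91 h), miR-669ao-3p (5.12 h) and miR-20b-5p (5.59 h), and the longest miR-15a-5p (22.9 h), miR-708-5p (19.1 h), miR-300-3p (18.6 h), miR-27b-3p (18.6 h) and miR-24-3p (18.3 h).

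The difference between fibroblast states was spread over nearly all miRNAs. MiR-17-3p and miR-19a-3p of the proliferative miR-17-92 cluster, and miR-34b-3p, a p53 target, were among those with the largest gain in CIMEF. Members of that cluster (miR-17-3p, miR-17-5p) and their paralog miR-93-5p were shorter-lived in ESC. Between ESC and DMEF few miRNAs differed, among them miR-125b-5p, which is abundant in fibroblasts and whose courses lay far apart in both lines. Dividing cells dilute their miRNAs, and the values include that.

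Of 119 miRNAs inside the limits in both lines, limma called 91 longer in CIMEF than in DMEF and 0 shorter, and 116 were longer with a median log2 of 2.34. MiR-669b-5p differed most (log2 5.21, SE 0.81, adjusted p = 1.8e-08), followed by miR-145a-3p (5.19), miR-17-3p (5.11), miR-19a-3p (4.89) and miR-34b-3p (4.73). The same SE applied to every miRNA named between lines, since the fit took a spread shared over all miRNAs. Neither this SE nor the p-values show the spread of each miRNA between courses. CIMEF courses lay far apart for miR-145a-3p (1377 and 65.3 h) and miR-34b-3p (71.4 and 1607 h). They were closer for miR-669b-5p (169 and 456 h), miR-17-3p (138 and 73.0 h) and miR-19a-3p (409 and 155 h). Calls fell to 15 without DMEF course 1 and to 0 without DMEF course 2 (limma, 41 at an unadjusted p), and 0 passed with times up to 24 h. With times up to 24 h, 151 and 115 fits of the CIMEF courses lay at the upper limit, and 25 miRNAs could be tested. Of these, 21 were longer in CIMEF (median log2 1.64). Centring was chosen after seeing the data. Centred on the course median, 2 were called longer and 3 shorter in CIMEF, with a median log2 of -0.074. Centred on the 68 miRNAs measured in every course, whose medians in the CIMEF courses were 197 and 125 h against 83.3 and 51.3 h for all miRNAs, 2 were called longer and 20 shorter, with a median log2 of -0.89. With EU share over input share, in which the shares of a library cannot all rise together, the median log2 was -0.22 and 3 were called. Against CIMEF, 30 of 35 were shorter in ESC (median log2 -2.88), led by miR-17-3p (-6.06), miR-17-5p (-5.02), miR-93-5p (-4.90), miR-20a-3p (-4.59) and miR-19a-3p (-4.54). Among these the CIMEF courses lay farthest apart for miR-93-5p (74.6 and 742 h). Without CIMEF course 2 there were 46 calls, with the sequencing standards 10 and with times up to 24 h 1, and centred on the course median 2 were longer and 4 shorter (median log2 -0.17). Centred on the miRNAs of all courses 13 were longer and 1 shorter (0.96). Only 5 miRNAs could be tested with times up to 24 h, of which 0 were longer in ESC (median log2 -1.48). With EU share over input share 0 passed (limma, 2 at an unadjusted p). Against DMEF, 2 of 75 were longer in ESC (miR-376b-3p 3.18, miR-154-3p 2.404) and 3 shorter (miR-125b-5p -5.05, miR-423-3p -3.01, miR-181c-5p -2.68), with a median log2 of -0.38. Courses lay far apart for miR-125b-5p, with 7.17 and 0.449 h in ESC and 161 and 21.9 h in DMEF. None passed (limma) without DMEF course 1 (6 at an unadjusted p) or course 2 (8), with times up to 24 h (8), without the 1 h libraries (13) or with EU share over input share (5), and 2 without either ESC course. Without either CIMEF course 8 passed. The median log2 was -0.68 without DMEF course 2, 1.55 with the sequencing standards, 1.23 with all standards summed, -0.072 centred on the course median and 0.24 centred on the miRNAs of all courses. Across the 68 miRNAs measured in every course, medians were 197 and 125 h in CIMEF, 21.4 and 13.2 h in DMEF, 9.77 and 12.3 h in ESC and 36.4 h in the knockout.

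Guide strands outlived their passenger strands. A miRNA hairpin gives a guide, which Argonaute proteins hold and protect, and a passenger, which is mostly discarded. Let-7b, for example, had a long-lived 5p guide and a short-lived 3p passenger in CIMEF. The test asks whether the more abundant strand is also the more stable. The guide is picked here by its abundance, and a longer life itself raises abundance. The difference is therefore partly built in and does not show what strand choice does.

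In CIMEF the guide lasted longer in 34 of 39 hairpins, with a median log2 ratio of 3.33 (10.1-fold). In DMEF it did so in 38 of 54, with 1.88 (3.68-fold), and in ESC in 9 of 10, with 1.62 (3.07-fold). The two-sided permutation p was 1e-05 in CIMEF and DMEF, the smallest that 100000 resamples can give (adjusted p = 1.5e-05), and 0.00584 in ESC (adjusted p = 0.00584). Hairpins are not independent replicates, so these p-values measure spread across hairpins and not between cultures. Let-7b-5p had 51.3 h and let-7b-3p 2.93 h in CIMEF. With the sequencing standards the median log2 ratio was 2.14 in CIMEF and 0.24 in DMEF. In CIMEF it was 1.64 with all standards summed and 2.29 without subtraction of the 0 h value. It was 2.29 there without course 1 and 2.36 without course 2. Differences between lines did not pass, with adjusted p = 0.375 for CIMEF against DMEF over 22 hairpins (permutation), 0.375 for CIMEF against ESC over 3 (exact) and 0.5625 for DMEF against ESC over 5 (exact). With 3 or 5 hairpins the exact test cannot reach 0.05, so these last comparisons could not pass.

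**Figure D3:**
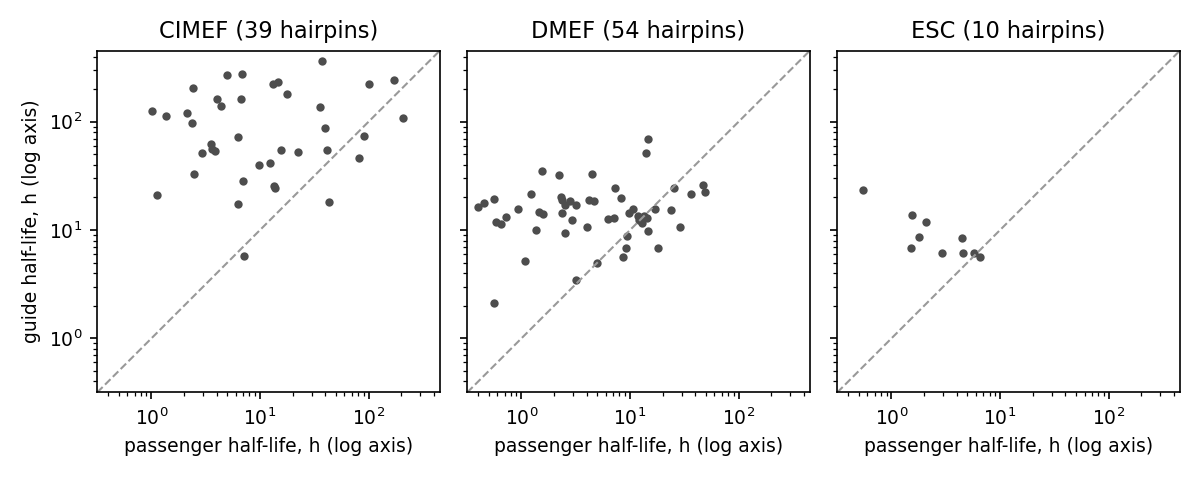
Half-life of the guide against that of the passenger of each hairpin (points; hours, log axes) in CIMEF, DMEF and ESC, as the geometric mean of both courses; the dashed line marks equal half-lives. Points above the line number 34 of 39, 38 of 54 and 9 of 10.

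In fibroblasts, where let-7 and mesenchymal miRNAs dominate, longer-lived miRNAs were also more abundant. In ESC, where miR-290-295 members are abundant, no such relation passed. The question is how production and decay share in setting levels.

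The production rate is the fitted plateau times the decay rate. The plateau is itself a measure of abundance, so the relation of production with input share is in large part built in and does not show what sets levels. Log2 production rate correlated with log2 input share across miRNAs, which are not independent replicates, in CIMEF (r = 0.61, rho = 0.54, 159 miRNAs), DMEF (r = 0.81, rho = 0.74, 233) and ESC (r = 0.90, rho = 0.85, 112). Without the 2 miRNAs farthest from the median, r was 0.58, 0.80 and 0.89. Log2 half-life correlated with input share in CIMEF (r = 0.64, rho = 0.63, 0.63 without the 2 farthest) and DMEF (r = 0.38, rho = 0.40, 0.38 without them). In ESC r was 0.11 and rho 0.07 (0.02 without them; permutation p = 0.266, adjusted p = 0.266). The other 5 of the 6 relations had a two-sided permutation p of 1e-05, the smallest that could be given (adjusted p = 1.2e-05). With EU share over input share, no production relation passed and the half-life relations turned negative. The relations were not recomputed with other standards or without subtraction of the 0 h value. Without ESC course 1, r of half-life in ESC was 0.23 over 180 miRNAs and passed (permutation p = 0.00159).

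Among families, the miR-17-92 group was the longest-lived in CIMEF, and the imprinted Dlk1-Dio3 cluster, transcribed as one long noncoding RNA, was short-lived in DMEF, as was the placental Sfmbt2 cluster. The model takes input as steady, but input of miR-92a-3p, miR-17-5p and miR-20a-5p rose in CIMEF, which lengthens a fitted half-life, and that of miR-376a-3p and miR-136-5p fell in DMEF, which shortens it. Part of these family differences can therefore come from changing levels. In ESC no family stood apart, miR-290-295 included.

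In CIMEF the 7 measured guides of the miR-17-92 group had a median half-life of 223 h against 58.5 h for other guides (log2 1.93, permutation adjusted p = 0.0089). Members of a list, many of them from 1 transcript, are not independent replicates. The p-values of these list tests measure spread across miRNAs and not between cultures. The other 4 lists did not pass there, with medians of 94.1 h for let-7, 40.9 h for miR-15/16, 69.8 h for mesenchymal miRNAs and 156 h for miR-29 and miR-30. In DMEF the 24 Dlk1-Dio3 guides had 8.43 h against 16.1 h (log2 -0.93, adjusted p = 1.4e-04), and the 16 Sfmbt2 guides 10.5 h against 15.6 h (adjusted p = 0.0437). The other 5 lists in DMEF did not pass, but mesenchymal miRNAs passed as longer-lived without subtraction of the 0 h value (adjusted p = 0.0442) and without the 1 h libraries, a setting chosen after seeing the data (adjusted p = 0.0381). In ESC none of 6 lists passed by permutation, and mesenchymal miRNAs came closest, with 15.6 h against 9.77 h over 9 guides (permutation p = 0.0306, adjusted p = 0.183). The miR-290-295 and miR-302 guides had 8.55 h against 10.3 h over 12. No list passed in CIMEF with the sequencing standards, with all standards summed, with a lag of 0.5 h or without CIMEF course 1. In DMEF only the Dlk1-Dio3 cluster passed with either other sum of standards, with a lag, with times up to 24 h, with the unweighted fit and without DMEF course 1. With a mean input count of 500, neither that cluster nor the Sfmbt2 cluster had enough measured guides in DMEF to be tested. With EU share over input share 0 passed in either line by permutation.

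Loss of Cyrano went with more miR-7a-5p. Cyrano carries a site that pairs extensively with miR-7 and is known to direct its destruction, and miR-7a-5p stood far above wild type in every knockout input library. Its partner strand miR-7a-1-3p, made from the same hairpin, was higher by much less. The X-linked miR-672 pair and miR-149-5p were also higher, and miR-181c and miR-181d lower. The comparison asks what the noncoding RNA does to miR-7 and to its half-life.

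Cyrano itself (Oip5os1, ENSMUSG00000085438; chromosome 2, 119594296 to 119600746) had 12333 and 12248 counts in the CIMEF mRNA libraries (496 ± 52.8 CPM), 149 ± 69.4 CPM in DMEF and 65.3 ± 3.05 CPM in ESC (SD, n = 2). The knockout has no mRNA library, so the loss of Cyrano could not be checked. MiR-7a-5p averaged 95.6 ± 34.8 and 85.2 ± 21.6 CPM in the CIMEF courses and 2750 ± 645 CPM in the knockout (SD over the 6 shared times). The lowest knockout library had 1731 CPM and the highest wild-type library 142 CPM. The log2 difference was 4.96 (SE 0.15, adjusted p = 6.8e-11), against -0.40 between both wild-type courses, and 5.21 (adjusted p = 0.0113) with counts summed per course, where the knockout is 1 sample and the spread comes from the other lines. MiR-7a-1-3p differed by 0.996 (SE 0.11). In EU libraries miR-7a-5p was higher by 2.24 (SE 0.34, adjusted p = 3.8e-04) and miR-7a-1-3p by 1.32 (SE 0.23); with counts summed per course the EU difference of 2.06 did not pass (adjusted p = 0.242). MiR-7b-5p had 23 counts over the knockout input libraries and was filtered out. The annotation lists Mir7-1 on chromosome 13 at 58392779 to 58392886, inside Hnrnpk, Mir7-2 on chromosome 7 at 78888277 to 78888373 and Mir7b on chromosome 17 at 56242988 to 56243098.

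**Figure D4:**
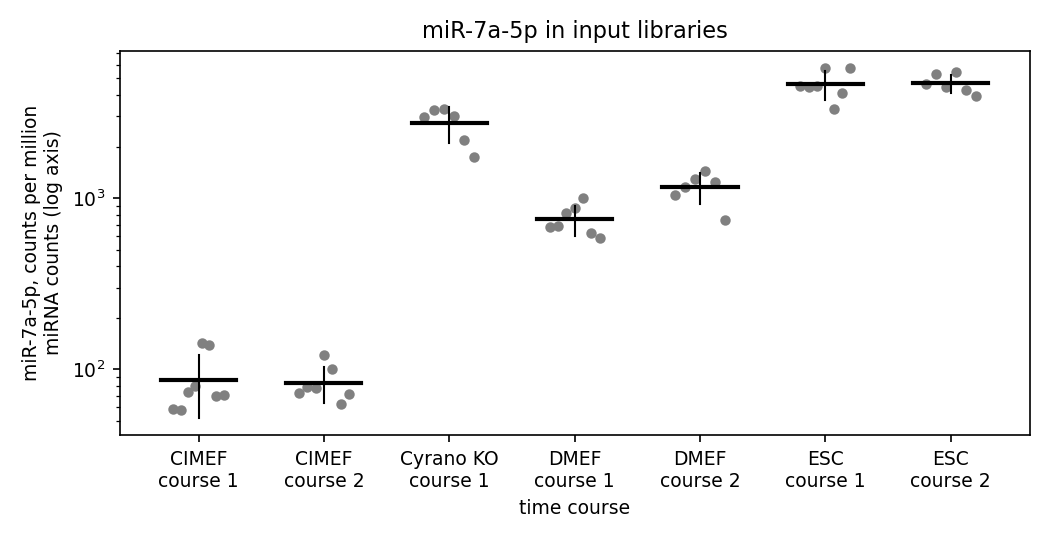
Level of miR-7a-5p (CPM, log axis) in each input library (points) of the 7 time courses, with the mean (wide bar) and SD (thin bar) over all times of a course. Knockout (KO) libraries lie between 1731 and 3310, and wild-type CIMEF libraries at the shared times between 62.4 and 142.

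Over all miRNAs, 122 were higher and 103 lower of 517 in knockout input libraries, and 77 higher and 49 lower of 383 in EU libraries. Both wild-type courses differed from each other in 389 (input) and 247 (EU), so counts of this size also arose between courses of 1 genotype. With counts summed per course, 7 were called in input and 0 in EU libraries (edgeR). DESeq2 called 195 in EU libraries, and without CIMEF course 2 there were 389 in input and 226 in EU libraries. Input differences with the smallest p were miR-149-5p (log2 1.88), miR-672-3p (3.93), miR-205-5p (6.32), miR-672-5p (4.10) and miR-99a-5p (1.80) upward, and miR-181c-5p (-1.98), miR-30a-5p (-0.73), miR-181d-5p (-1.68), miR-181c-3p (-1.99) and miR-1298-5p (-4.21) downward. In EU libraries they were miR-196a-5p (6.34), miR-672-5p (3.29), miR-672-3p (3.62), miR-423-3p (1.29) and miR-149-5p (1.74), and miR-181c-5p (-2.13), miR-181d-5p (-1.97), let-7b-5p (-1.11), miR-100-5p (-1.05) and miR-301a-3p (-0.84).

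The fitted half-life of miR-7a-5p was 11.7 h in the knockout and 4.82 and 3.54 h in the CIMEF courses, a log2 difference of 1.498 (SE 0.99) that did not pass (limma, adjusted p = 0.227). Most other miRNAs went the opposite way, with a median log2 of -1.61 over 150 miRNAs, 29 shorter and 1 longer. Relative to the course medians, an alternative chosen after seeing the data, miR-7a-5p lasted longer by 3.22 (SE 0.58, adjusted p = 0.0271), and relative to the 68 miRNAs of all courses by 3.61 (SE 0.42, adjusted p = 0.0209). The knockout has 1 half-life per miRNA, so the SE and p of all its half-life differences come from the spread of the other courses. In the knockout, miR-503-5p had a fitted half-life of 0.305 h and let-7e-3p one of 0.298 h. Both lie below the first knockout time of 2 h and near the lower limit of 0.25 h, so the size of their differences is uncertain. The CIMEF courses lay far apart for miR-145a-3p (1377 and 65.3 h) and for miR-219a-5p. With these limits, shorter in the knockout were miR-219a-5p (-5.24), miR-145a-3p (-4.40), miR-503-5p (-4.24), let-7e-3p (-3.94) and miR-19a-3p (-3.89), and longer miR-29b-1-5p (3.00). None was called (0, limma) with the sequencing standards (53 at an unadjusted p, median log2 -2.09), with all standards summed (12, -0.57), without the 1 h libraries (48, -1.48), with times up to 24 h (5, -0.67) or without either DMEF course (33 each, -1.61). There were 2 calls with either centring, 3 with a mean input count of 500, 9 with the unweighted fit, 17 without CIMEF course 1 and 58 without CIMEF course 2. In the other lines miR-7a-5p had 2.43 and 1.84 h (DMEF) and 3.54 and 5.44 h (ESC), and neither difference from CIMEF passed in limma (adjusted p = 0.266 and 0.914). Centred on the course median, miR-7a-5p was longer-lived in ESC than in CIMEF (log2 2.80, adjusted p = 0.00264), and the difference between CIMEF and DMEF did not pass (-1.45, adjusted p = 0.0779). Centred on the miRNAs of all courses both passed (3.93, adjusted p = 4.8e-04, and -2.26, adjusted p = 0.0148).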

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

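Only the following tests were chosen after the results they concern had been seen. They are the random splits of libraries and courses, the precursor test, the test of the standards and the test of background subtraction.

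The slopes of input miRNAs on labelling time differed between lines for 25 miRNAs in CIMEF against DMEF, 14 in CIMEF against ESC and 5 in DMEF against ESC. Regrouping the courses gave at most 2, 0 and 0 calls. Each regrouping has only 3 splits (1 of 3 reached the count in each case, the real one), which is too few to exclude chance.

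The number of miRNAs that differed between knockout and wild-type libraries was set against random splits of the same libraries. In input libraries 2 of 100 splits, the real one included, gave at least 225 calls, and the highest other split gave 234. In EU libraries 1 of 100 did, with 126 calls against 113 in the highest other split. These splits mix the libraries of a course as if they were independent, so they decide nothing about differences between courses. Splits that set a whole wild-type course against the other courses gave 328 and 245 calls in input and 206 and 147 in EU libraries, more than the knockout did, which points to differences between courses as such.

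The higher level of miR-7a-5p in knockout input libraries may be the known effect of Cyrano on miR-7. It cannot be told apart from an ordinary difference between time courses, because only 1 knockout course exists. Between both wild-type courses 78 tested miRNAs differed at least as much, and 72 of them lie in the Dlk1-Dio3 cluster. With counts summed per course miR-7a-5p had an adjusted p = 0.0113, but the knockout is 1 sample there and the spread comes from the other lines, so this does not settle it. More precursor was argued against as the whole cause, since miR-7a-5p exceeded miR-7a-1-3p of the same hairpin by a log2 of 3.97. Reads of miR-7b-5p were argued against too, as its counts were 0.0195% of those of miR-7a-5p. A second knockout course, with mRNA libraries, would settle the first point.

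Half-lives were shorter in the knockout course than in both wild-type CIMEF courses, with a median of 19.8 h. The missing 1 h library was argued against, since the lower wild-type median was 46.9 h without the 1 h libraries. Background subtraction was argued against as well, since the lower wild-type median was 37.6 h without it and that of the knockout 16.6 h. The test of the standards did not exclude them as the cause. With all standards summed the knockout median was 21.0 h, between the wild-type medians of 18.1 and 56.0 h, so the shorter half-lives could come from the recovery of the standards. With the sequencing standards the knockout median was 3.62 h, below the 17.8 and 16.6 h of the wild-type courses. With the 3 standards of the first fit it was 19.8 h, below 83.3 and 51.3 h. Within either kind the knockout median was lower, but this does not decide whether the choice of standards is the cause. In the 2 h EU libraries the sequencing standards had 399 counts in the knockout, 572 in CIMEF course 2 and 355542 in CIMEF course 1. Medians on these standards therefore do not treat courses alike. Differences between courses in the recovery of the standards stay open. An amount of each standard recorded per library would settle this.

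Passenger strands had shorter half-lives than guides. Lower counts of passengers were argued against as the cause, since thinning guide counts to the level of the passenger left at least 0.820 of the median log2 ratio in each line. Thinning addresses counting error only, and not that the guide was picked by its abundance.

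Some features were counted but not used here. The 3 standards of the EU libraries had more counts than a count of 0 allows in 6 input libraries, with at most 27, in the knockout at 24 h. The standard of 30 nucleotides reached 161 counts in EU libraries. Size markers reached 563463 counts in EU libraries and 736525 in input libraries.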

How the results depend on the processing

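Each result was recomputed under other settings, and a result is described as moved when a value shifted by more than 1.5 times, and as weaker when a call ended. Chosen after seeing the data were the sequencing standards, all standards summed, the fits without the 1 h libraries, centring on the course median or on the miRNAs shared by all courses, limits kept at the grid edge, the control splits, and the fit without Gm42418. Where a course was left out and a line kept a single course, the fit assumes that the lone course varies like the other groups. Why a value moved was not tested, except where the construction of a setting shows it.

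For miRNA levels, 9 of 33 values moved. Between CIMEF and DMEF edgeR called 0, DESeq2 110, and edgeR 315 with each input library at the shared times as a sample, where time points stand in for replicates. ESC against DMEF gave 598 with that last setting. Leaving out a course gave 0 to 207 calls for CIMEF against DMEF (49 without CIMEF course 2 and 207 without CIMEF course 1), 208 to 582 for ESC against DMEF and 268 to 569 for ESC against CIMEF, the lowest without ESC course 1 in both. For mRNA 1 of 30 values moved. Leaving out a library gave 3605 to 8379 calls for CIMEF against DMEF, with the lowest count without DMEF replicate 2. Without Gm42418 the contrast gave 7259.

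Among single genes, 1097 of 1195 miRNA values kept call and direction and 98 were weaker. For mRNA 2551 of 2628 were kept and 77 were weaker. None turned direction.

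A replicate block, which adds the replicate number as a term, gave 0, 368 and 421 miRNA calls for CIMEF against DMEF, ESC against DMEF and ESC against CIMEF, and 6699, 10656 and 13372 for mRNA. With the replicate block the half-life calls were 78, 4 and 30. Correlations between lines of the difference of replicate 2 from replicate 1 were 0.26, 0.11 and 0.08 for miRNA and 0.06, 0.00 and -0.02 for mRNA, so replicates of the same number shared little.

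The gene-set tests all moved. With an estimated correlation, no list passed camera in any of the 6 tests, which are CIMEF against DMEF (0), ESC against DMEF (0) and ESC against CIMEF (0) for miRNA and the same contrasts for mRNA (0, 0 and 0). The estimated correlation comes from few replicates.

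For the slopes on labelling time, leaving out a course gave 29 to 87 calls in CIMEF, 23 to 50 in DMEF and 0 to 8 in ESC. The lowest counts came without course 2 in CIMEF, without course 1 in DMEF and without course 2 in ESC. Of 104 values for named miRNAs, 84 were kept and 20 were weaker.

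Median half-lives moved in 32 of 63 values. With EU share over input share they were 0.25 h in both CIMEF courses (0.25 and 0.25 h) and in the knockout (0.25 h), which is the lower limit of the grid, 0.373 and 0.311 h in DMEF, and 0.359 and 0.445 h in ESC. Of 1754 fits with this setting, 911 (51.9%) sat at the lower limit, because the shares of a library cannot all rise together. Without subtraction of the 0 h value, CIMEF course 1 had 52.98 h, and ESC 8.37 and 8.97 h. With times up to 24 h, CIMEF course 1 had 240 h, which is the upper limit of that grid, and DMEF course 1 had 16.9 h. A lag of 0.5 h gave 9.09 and 6.60 h in DMEF and 5.17 and 5.93 h in ESC. A mean input count of 500 gave 73.0 h in CIMEF course 2 and 16.7 h in DMEF course 1. The unweighted fit gave 12.2 h in ESC course 2.

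With the sequencing standards the medians were 17.8 and 16.6 h in CIMEF, 3.56 and 1.51 h in DMEF, 16.1 and 3.48 h in ESC and 3.62 h in the knockout. With all standards summed they were 18.1 h in CIMEF course 1 and 3.63 and 4.80 h in DMEF. Without the 1 h libraries they were 9.0 h in DMEF course 2 and 7.81 and 8.66 h in ESC.

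The half-life difference between CIMEF and DMEF kept its direction in all settings but 3. With EU share over input share 3 miRNAs were called and the median log2 was -0.22. Centred on the course median, 2 miRNAs were called longer and 3 shorter in CIMEF (5 in all), against 91 and 0 before, and the median was -0.074. Centred on the 68 miRNAs shared by all courses, 2 were longer and 20 shorter (22 in all), with a median of -0.89. Centring removes the shift of the reference miRNAs, so such a median only compares the tested miRNAs with the reference. The sequencing standards gave a median of 3.10. Times up to 24 h left 25 miRNAs to test and gave 0 calls in limma and a median of 1.64. Without 1 course at a time the calls were 0 to 131, with 0 without DMEF course 2 and 15 without DMEF course 1. MiR-7a-5p had a log2 of -1.45 centred on the course median and -2.26 centred on the shared miRNAs, against a value above 0 in the other settings.

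Between ESC and CIMEF the calls were 51 without subtraction, 0 with EU share over input share (median log2 0.20), 6 centred on the course median (2 longer and 4 shorter in ESC, median -0.17), 14 centred on the shared miRNAs (13 longer and 1 shorter, 0.96), 10 with the sequencing standards (-1.93), 1 with times up to 24 h (-1.48) and 19 with the unweighted fit. Times up to 24 h left 5 miRNAs to test. The median was -2.17 with all standards summed and -3.48 with a lag. Leaving out a course gave 24 to 46 calls, the most without CIMEF course 2. MiR-7a-5p had -0.33 with a lag, -0.89 with times up to 24 h and -0.22 to 0.40 when a course was left out (-0.14 without CIMEF course 2), and none of these passed.

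Between ESC and DMEF the calls were 12 without subtraction, 0 with EU share over input share (median log2 0.042), 3 with all standards summed (all longer in ESC, median 1.23), 7 centred on the course median (5 longer and 2 shorter, -0.072), 8 centred on the shared miRNAs (7 longer and 1 shorter, 0.24), 9 with a lag, 3 with a mean input count of 500, 0 with times up to 24 h (0.025), 3 with the unweighted fit and 0 without the 1 h libraries. With the sequencing standards 6 were longer and 0 shorter, with a median of 1.55. Leaving out a course gave 0 to 8 calls and medians of -0.68 to -0.18, with 0 calls without either DMEF course. MiR-181c-5p had 0.69 with the sequencing standards. Of 272 values for named miRNAs in the 3 contrasts, 208 were kept, 54 were weaker, 3 stronger and 7 turned direction.

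For guide and passenger strands, EU share over input share left 1 hairpin in CIMEF (log2 0.41), 4 in DMEF (-0.40) and none in ESC. Times up to 24 h left 1 hairpin in CIMEF (0.55). The other settings kept the direction in every line, and the lowest CIMEF median among them was 1.64, with all standards summed. Limits kept at the grid edge gave 3.82 in CIMEF, 2.58 in DMEF and 2.82 in ESC.

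Correlations with EU share over input share were 0.15 in CIMEF, 0.11 in DMEF and 0.21 in ESC for the production rate, and -0.30, -0.24 and -0.34 for the half-life. In ESC r of half-life was 0.062 to 0.234 when a course was left out, with the highest value, which passed, without ESC course 1 (permutation p = 0.00159).

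Among lists, 0 passed in CIMEF with EU share over input share, with a lag, with the sequencing standards and with all standards summed, and 0 to 1 when a course was left out (0 without CIMEF course 1). In DMEF 0 passed with EU share over input share. With a mean input count of 500, 0 of 5 lists passed, and the Dlk1-Dio3 and Sfmbt2 clusters had too few measured guides to be tested. The Dlk1-Dio3 cluster alone (1) passed with a lag, with times up to 24 h, with the unweighted fit, with the sequencing standards and with all standards summed. There 1 to 2 passed when a course was left out (1 without DMEF course 1). Mesenchymal miRNAs, which did not pass in the first fit, passed as longer-lived in DMEF without subtraction of the 0 h value (adjusted p = 0.0442) and without the 1 h libraries (adjusted p = 0.0381). The miR-17-92 group in CIMEF had a log2 of -0.52, and the Dlk1-Dio3 cluster in DMEF 0.094, with EU share over input share. Of 30 values for single lists, 17 were kept, 11 were weaker and 2 turned direction.

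For the knockout, input calls were 389 between both wild-type courses and 7 with counts summed per course. EU calls were 195 with DESeq2, 247 between both wild-type courses, 206 when CIMEF course 1 was set against the other courses, and 0 in edgeR with counts summed per course, where miR-7a-5p had a log2 of 2.06 (adjusted p = 0.242) and the knockout is 1 sample. Leaving out a course gave 335 to 389 input calls and 179 to 226 EU calls, the most without CIMEF course 2 in both. Named miRNAs kept their call in 47 of 55 input values (8 weaker) and in 48 of 60 EU values (12 weaker).

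Half-life calls in the knockout were 1 with EU share over input share (median log2 0.41), 0 with all standards summed (-0.57), 2 centred on the course median (both longer, 0.11), 2 centred on the shared miRNAs (both longer, 0.50), 3 with a mean input count of 500, 0 with the sequencing standards (-2.09), 0 with times up to 24 h (-0.67), 9 with the unweighted fit (-1.58) and 0 without the 1 h libraries (-1.48). Leaving out a course gave 0 to 58 calls, with 0 without either DMEF course, since the DMEF courses enter the estimate of spread, while the median stayed at -1.61. MiR-7a-5p had 3.22 centred on the course median and 3.61 centred on the shared miRNAs, with a spread taken from the other courses. Of 78 values for named miRNAs, 35 were kept and 43 were weaker.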

Other observations

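MiR-142a-3p.1, miR-150-5p and miR-124-3p.1, known from blood and neurons, averaged 5343, 1951 and 3519 CPM in ESC. As summed levels, hematopoietic markers had 7338 CPM in ESC, 618 CPM in DMEF and 168 CPM in CIMEF. MiR-142a-3p.1 and miR-150-5p carried that sum, while miR-155-5p was lower in ESC than in DMEF (log2 -3.97), as was miR-223-3p (1 count in ESC, 56.0-fold, 95% interval 9.61 to 2255), and the list median was -2.27.

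Cyrano and miR-7a-5p ran in opposite order across the lines. Cyrano averaged 496, 149 and 65.3 CPM in CIMEF, DMEF and ESC, and miR-7a-5p averaged 95.6 and 85.2 CPM in the CIMEF courses, 767 and 1159 CPM in DMEF and 4646 and 4677 CPM in ESC. Its fitted half-lives (4.13, 2.12 and 4.39 h) did not follow that order. Centred on the course median, a setting chosen after seeing the data, the half-life in CIMEF differed from that in DMEF by a log2 of -1.45, which did not pass, and that in ESC from CIMEF by 2.80. Centred on the 68 miRNAs shared by all courses, the values were -2.26 and 3.93. With either centring CIMEF, the line with most Cyrano, had the shortest half-life, so the order depends on the centring. With 3 lines the order itself was not tested.

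The CIMEF courses differed most in the Dlk1-Dio3 cluster, with miR-539-3p apart by a log2 of 8.80 in input libraries and miR-337-3p by 8.77 in EU libraries.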
